A study of Mus musculus with 2 samples.

How the data were processed

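The series holds 2 RNA-seq libraries of mouse lung dissected on embryonic day 16.5, which the labels number as biological replicates 1 and 2 of a single group. Each library was made from a pool of male and female embryos of strain B6NCrl. The labels state 41 embryos for replicate 2 and give no number for replicate 1. Per the labels' protocols, RNA was extracted with an Ambion mirVana kit, 10 ng of RNA longer than 200 nt entered each library, spike-ins were added, whose rows carry ERCC names, and a manual for a SMARTer kit for low RNA input is linked among the protocols. The labels call the assay total RNA-seq, and no strand setting, aligner version or quantifier version is given in the sources used here.

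For each library the authors deposited a table of genes and a table of transcripts, quantified on the mouse build mm10 with GENCODE annotation M4, per the notes deposited with the files. The expected counts the authors deposited are estimates of the number of reads per gene or transcript, in which a read that matches several genes is divided among them. The TPM values, per the file headers, are each transcript's share of its library after division by effective length, scaled to the same total in each library, and the spike-ins are part of that total. The FPKM values the authors deposited divide by effective length and by the reads assigned. The score columns deposited beside TPM are the lower and upper bounds of a credibility interval within the library. The TPM value can lie outside them, as for Sftpc in replicate 1, at 10883 TPM with bounds of 10599 to 10693 TPM. The percent values deposited in the transcript tables give a transcript's share of the TPM of its gene. The posterior mean estimates of counts and TPM in the same tables, per the file headers, are a second estimate beside the maximum likelihood values. The column layout is that of RSEM, although no source used here names the tool. Effective length was 99 nt shorter than the annotated length for features longer than that.

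Symbols, annotation classes and coordinates came from GENCODE M21, a later annotation of the same build, matched by gene identifier without its version. This matched 42462 of the 43346 gene rows. The 884 rows without a match held 0.173% of the expected counts in replicate 1 and 0.171% in replicate 2 and kept their identifiers. A further 26248 rows carry bare numbers in place of gene identifiers and entered no comparison. Of 556 places on the gene lists, 2 (Ahsp and Snhg1) had no matching row and were not analysed here. Of 103639 rows for transcripts of genes, 101510 were matched.

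Total expected counts were 38852470 in replicate 1 and 27145411 in replicate 2. A gene of 2 kb with 0 counts has an upper limit of 0.0574 TPM in replicate 1 and 0.0810 TPM in replicate 2, from the limit of 3 counts that a count of 0 allows, which covers counting error only.

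A single group allows no comparison between conditions, so the results describe levels, ratios within a library, and the spread between the replicates. Every mean is given ± SD over n = 2. The smallest two-sided p that an exact sign-flip test can reach with 2 replicates is 0.5, so no test between the replicates was made and no p-value is given. A gene counted as detected at 1 TPM or more in both replicates. The level of each of 51 gene lists is the median TPM over its measured members, set against 10000 random lists of as many genes coding for protein. Differences between the replicates are on the log2(TPM + 1) scale, replicate 2 minus replicate 1, which understates the difference of low genes. They were counted at 2-fold or more among genes with a mean of at least 1 TPM. For each list with at least 3 members at a mean of 1 TPM, the median difference was placed among 10000 random lists of the same size matched on mean expression in 10 bins. A list outside the central 95% was described as standing apart, which describes these libraries only. The sign of a gene ratio was taken to hold when both replicates had it and the mean log2 ratio exceeded 2 SD.

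Expected counts of gene rows were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, which gave TMM scaling and the common dispersion with an intercept alone, and for DESeq2 1.42.0, which gave size factors for the alternatives. Other steps used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and the plots used matplotlib 3.10.9. The dispersion step was tested on simulated counts with a coefficient of variation of 0.05, 0.1 and 0.2 and returned 0.04997, 0.1001 and 0.2. In simulated libraries with 200 genes changed among the 15493 compared, the count at 2-fold recovered 1 of 67 genes changed 1.5-fold, 24 of 67 changed 2-fold and 61 of 66 changed 4-fold, with 113 unchanged genes called. Of 16 lists given a simulated log2 shift, 10 stood apart at a shift of 0.25, 15 at 0.5 and 16 at 1, and 0 of 16 did so on the higher side without a shift.

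The lists, ratios, transcripts, size rules and most alternatives were set before the data were examined. Genes named in the text are the 10 with the highest mean TPM, up to 4 members of each list with the highest mean TPM, the lowest member of a list near 0, the 8 genes with the largest difference in each direction among those with a mean of at least 5 TPM, the genes of the ratios and of the transcript shares, and, in a list that stands apart, up to 4 members with the largest difference in its direction. The alternatives were other TPM minimums, pseudocounts, fold thresholds, estimates and scalings, and leaving out either replicate. A count restricted to genes coding for protein and a correction of the list differences for gene length and GC content were added after the data were seen. GC content came from the longest annotated transcript and was available for 15383 of the 15493 genes compared.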

Results

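Gene expression was measured by RNA-seq in the whole lung of mouse embryos on embryonic day 16.5, an age at which the branching epithelial tree has been laid down and the distal airspaces begin to differentiate. The 2 libraries are biological replicates of 1 group, each from a pool of male and female embryos, so the data describe which genes this tissue expressed and how far separate pools differed. Replicate 1 held 38852470 expected counts and replicate 2 held 27145411. Values below are mean ± SD over these replicates (n = 2), and no difference between them was tested.

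Haemoglobin, surfactant and signal recognition particle RNA were among the most abundant RNAs, and the 10 highest genes of each replicate together took 10.05% of TPM in replicate 1 and 11.03% in replicate 2. The adult alpha globin gene Hba-a2 had the highest level, 20247 ± 1386 TPM, and Hbb-bs, Hba-a1 and Hbb-bt followed at 11246 ± 1506, 7769 ± 899 and 6547 ± 874 TPM. Sftpc on chromosome 14 (70520949 to 70524081, minus strand, build mm10), which encodes surfactant protein C of the distal epithelium, reached 12528 ± 2326 TPM. Rn7s1 and Rn7s2, nearly identical genes of the signal recognition particle RNA, were listed at 13707 ± 88.1 and 13708 ± 89.9 TPM, and the deposited credibility bounds of Rn7s2 in replicate 1 ran from 2064 to 20718 TPM. The mitochondrial gene mt-Atp6 stood at 6395 ± 392 TPM and Gm28437, annotated as a pseudogene on chromosome 1, at 6958 ± 383 TPM with credibility bounds of 2268 to 7250 TPM in replicate 1, and Actb at 6320 ± 195 TPM completed the 10 highest genes. Reads of near-identical copies (Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt, Rn7s1 with Rn7s2) and of mitochondrial genes with nuclear copies were divided by the authors' estimator, so the split among copies is uncertain.

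Genes coding for protein took 92.5 ± 0.155% of the expected counts. Long noncoding genes took 1.55 ± 0.116%, pseudogenes 1.57 ± 0.0970%, mitochondrial genes coding for protein 1.10 ± 0.0812%, small RNA genes 0.388 ± 0.00802% and the ERCC spike-ins 2.31 ± 0.0167%. Expressed as shares of TPM, which weights short RNAs more, the coding genes took 81.7 ± 0.0344%, small RNA genes 3.33 ± 0.0679%, pseudogenes 5.04 ± 0.218%, long noncoding genes 1.75 ± 0.0945%, mitochondrial genes coding for protein 2.31 ± 0.249% and the spike-ins 5.09 ± 0.0963%. At 1 TPM or more in both replicates, 14825 genes were detected, of which 13197 code for protein and 710 are long noncoding. Malat1, a nuclear long noncoding RNA, was at 4766 ± 382 TPM, and Gas5 and Meg3 were at 541 ± 22.7 and 409 ± 60.6 TPM. The Malat1 level rests on a short effective length. In replicate 1 it had 48885 expected counts at 4496 TPM, whereas Col1a1 had 181014 at 1192 TPM. Its TPM therefore depends on how reads were assigned among its transcripts, and its size is uncertain. Over the 6 measured members of the list named nuclear long noncoding, which includes Gas5, the median was 217 ± 36.5 TPM. It falls in a gap between Meg3 and Xist, the latter at 25.1 ± 12.4 TPM. Where in the cell the listed RNAs lay was not measured.

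Epithelial genes of the distal lung were high. The 13 genes of alveolar type 2 cells and surfactant were all above 1 TPM in both replicates, with a median of 98.4 ± 25.3 TPM. Besides Sftpc, the surfactant genes Sftpb and Sftpa1 were at 250 ± 28.2 and 223 ± 49.3 TPM, and Lyz2, which type 2 cells share with macrophages, was at 199 ± 26.3 TPM. The 10 genes of alveolar type 1 cells, the flat cells of gas exchange, had a median of 42.9 ± 5.09 TPM, led by Ager at 359 ± 57.9 and Igfbp2 at 187 ± 11.3 TPM. Distal tip progenitor genes were expressed beside them, with a median of 59.1 ± 1.55 TPM over 11 genes: the inhibitor of DNA binding Id2 was at 473 ± 35.7 TPM, the FGF-responsive factor Etv5 at 163 ± 8.36 TPM and the lung lineage factor Nkx2-1 at 69.8 ± 10.2 TPM. Pan-epithelial genes had a median of 168 ± 3.62 TPM over 11 genes, with Krt8 at 387 ± 27.8 and Epcam at 250 ± 0.474 TPM.

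In the conducting airway lists, secretory genes stood well above ciliated, basal and neuroendocrine genes. Scgb3a2, a secretoglobin of early club cells, was at 1095 ± 229 TPM, and the 8 secretory genes had a median of 49.3 ± 10.1 TPM. Ciliated cell genes had a median of 6.71 ± 0.629 TPM, with the ciliogenesis factor Foxj1 at 19.6 ± 1.42 TPM, and 9 of 11 members reached 1 TPM in both replicates. Basal cell genes had a median of 3.37 ± 0.926 TPM, of which Krt15 at 58.2 ± 11.2 TPM was the only member above 10 TPM in both replicates. Neuroendocrine genes had a median of 1.40 ± 0.460 TPM. Their highest member, Uchl1 at 46.4 ± 2.11 TPM, is also a neuronal gene.

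Mesenchymal, vascular and matrix genes were broadly expressed. Tcf21, a transcription factor of lung mesenchyme, was at 326 ± 6.97 TPM, and its list had a median of 48.5 ± 2.65 TPM over 10 genes. Smooth muscle genes had a median of 44.4 ± 0.626 TPM, led by Acta2 at 624 ± 46.8 TPM, and pericyte genes one of 15.7 ± 0.223 TPM, led by Cox4i2 at 85.3 ± 2.79 TPM. The 14 endothelial genes were all above 10 TPM in both replicates, with a median of 80.2 ± 0.548 TPM and Egfl7 at 314 ± 1.33 TPM. Lymphatic endothelial genes were lower, at a median of 11.2 ± 1.69 TPM, with the chemokine gene Ccl21a at 64.2 ± 2.34 TPM. All 25 extracellular matrix genes exceeded 10 TPM, with a median of 158 ± 1.74 TPM. Sparc reached 2077 ± 13.4 TPM, Mfap4 1376 ± 15.1 TPM and the fibrillar collagen genes Col3a1 and Col1a1 1341 ± 7.23 and 1090 ± 145 TPM. Mesothelial genes had a median of 15.2 ± 3.27 TPM with Upk3b at 37.3 ± 4.53 TPM, and cartilage genes one of 6.64 ± 0.223 TPM with Col9a3 at 32.0 ± 0.834 TPM.

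Blood cell genes were present at different levels. Erythroid genes had a median of 55.9 ± 2.35 TPM and a summed level of 46170 ± 4687 TPM, almost all of it globin. Macrophage and myeloid genes had a median of 17.9 ± 0.845 TPM, with Tyrobp at 48.8 ± 5.63 and C1qb at 44.8 ± 1.86 TPM. For megakaryocyte and platelet genes the median was 4.89 ± 1.06 TPM, with Pf4 at 61.6 ± 8.52 TPM. Lymphoid and thymus genes lay at a median of 1.53 ± 1.00 TPM, and 6 of 14 members reached 1 TPM in both replicates. Genes of peripheral neurons and of Schwann cells had medians of 1.92 ± 0.127 and 0.885 ± 0.332 TPM, with Stmn2 at 13.7 ± 1.53 and Erbb3 at 22.8 ± 0.488 TPM.

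Developmental signalling genes were expressed at moderate levels. The FGF list had a median of 19.1 ± 0.788 TPM, and Fgfr2, the receptor through which FGF10 drives branching, led it at 167 ± 3.57 TPM. The WNT list had a median of 15 ± 0.795 TPM, with Ctnnb1 at 376 ± 2.67 and Wnt2 at 72.5 ± 0.424 TPM. Hedgehog genes had a median of 11.4 ± 0.106 TPM, led by the antagonist Hhip at 83.8 ± 0.764 TPM. Medians were 22.4 ± 1.10 TPM for BMP and TGF-beta genes, led by Id3 at 470 ± 0.226 TPM, 13.9 ± 0.530 TPM for Notch genes, led by Hes1 at 32.6 ± 2.16 TPM, and 12.7 ± 0.311 TPM for retinoic acid genes. Among Hox genes of paralogue groups 1 to 6, Hoxb5 and Hoxa5 were highest at 35.9 ± 4.46 and 28.7 ± 2.47 TPM, and 11 of 18 reached 1 TPM in both replicates. Of the 21 Hox genes of groups 7 to 13, only Hoxa7 at 6.73 ± 0.707 TPM and Hoxb7 at 2.25 ± 0.587 TPM did so, and Hoxa13 was listed at 0 in both. The list medians were 1.85 ± 0.0919 and 0.0550 ± 0.00707 TPM.

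Growth and metabolic genes ranked high. Proliferation genes had a median of 169 ± 6.99 TPM over 13 genes, all above 10 TPM, with Cdk1 at 477 ± 13.5 and Birc5 at 271 ± 14.5 TPM. Imprinted genes had a median of 123 ± 1.68 TPM, with Mest at 1337 ± 71.1 TPM and Dlk1 at 612 ± 26.5 TPM. Ribosomal protein genes had a median of 881 ± 1.28 TPM, mitochondrially encoded genes 1207 ± 175 TPM and housekeeping genes 284 ± 8.23 TPM. The hypoxia and angiogenesis list had a median of 44.0 ± 0.247 TPM, led by the glycolytic gene Ldha at 1435 ± 52.2 TPM, whereas the angiogenic factor Vegfa was at 4.29 ± 0.651 TPM. Glucocorticoid response genes had a median of 50.6 ± 4.72 TPM with Tsc22d3 at 104 ± 6.14 TPM. Heat shock genes stood at 89.6 ± 0.166 TPM with Hspa8 at 1951 ± 13.2 TPM, immediate early genes at 11.3 ± 0.481 TPM with Btg2 at 111 ± 2.93 TPM, and interferon response genes at 2.02 ± 0.870 TPM with Bst2 at 43.5 ± 1.00 TPM. Genes of lung fluid and ion transport had a median of 10.6 ± 1.41 TPM, led by the sodium pump subunit Atp1b1 at 121 ± 10.8 TPM. RNAs that carry no poly(A) tail in most cells, such as the replication-dependent histone gene Hist1h4d at 390 ± 10.8 TPM and Rn7sk at 277 ± 52.2 TPM, had a median of 37.8 ± 1.55 TPM. Histone genes lie in clusters of close copies, so the level of a single member is uncertain.

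Genes of other organs ranged from near 0 to clearly present. Kidney genes had a median of 0.0250 ± 0.00707 TPM, with Umod listed at 0, and thyroid genes one of 0.140 ± 0.0424 TPM. Brain genes had a median of 0.208 ± 0.0955 TPM with Olig2 listed at 0, although Mbp was at 10.8 ± 0.445 TPM. Medians this low depend on the estimate: with the posterior mean TPM the list levels were 0.13 TPM for kidney, 0.325 TPM for thyroid, 0.145 TPM for Hox paralogue groups 7 to 13 and 1.52 TPM for Schwann cells. Cardiac muscle genes reached a median of 39.3 ± 13.0 TPM, with the atrial light chain gene Myl7 at 471 ± 133 TPM. Skeletal muscle genes had a median of 13.5 ± 10.7 TPM and liver genes one of 22.7 ± 25.0 TPM, where the SD came close to or passed the mean because the replicates differed. Y-linked genes had a median of 7.83 ± 4.70 TPM and the X inactivation list one of 7.96 ± 0.223 TPM, with Xist at 25.1 ± 12.4 TPM.

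**Figure D1:**
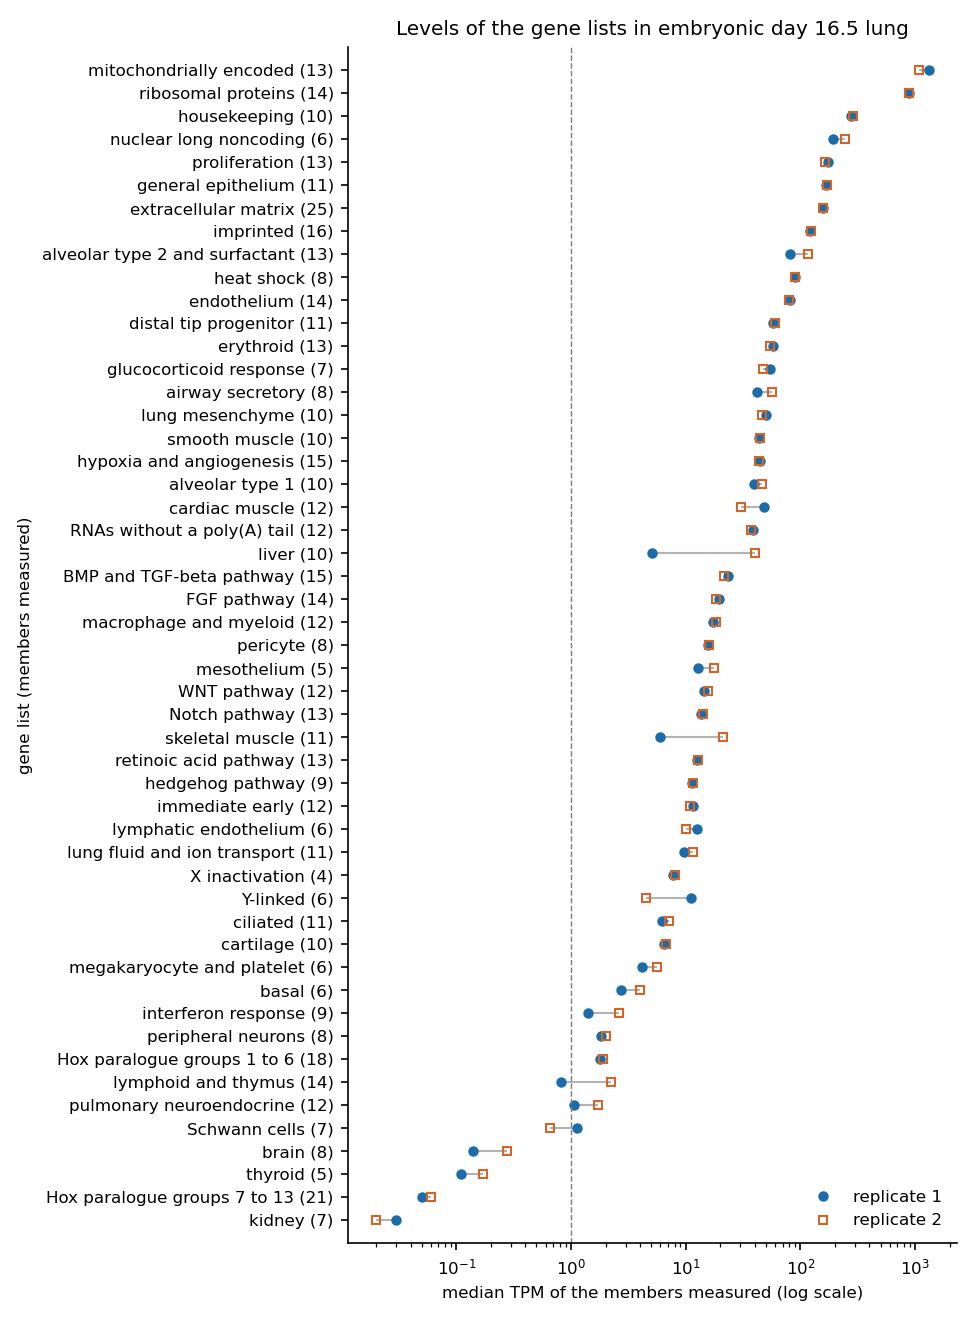
Median TPM of each of the 51 gene lists on a log axis, with replicate 1 as filled circles and replicate 2 as open squares, the number of measured members in parentheses and a dashed line at 1 TPM. Most lists lie at nearly the same level in both replicates, while the liver, skeletal muscle, lymphoid and thymus, and Y-linked lists are spread apart.

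Ratios between related genes within a library cancel its scaling, and their sign held in 18 of 20 pairs by the rule of 2 SD. Sftpc exceeded Sftpb by 5.64 ± 0.11 on the log2 scale and Ager by 5.12 ± 0.04. The tip progenitor gene Sox9 exceeded the airway gene Sox2 by 5.22 ± 0.36, with Sox2 at 1.21 ± 0.127 TPM. Epcam exceeded Pecam1 by 1.04 ± 0.08, Fgfr2 exceeded Fgfr1 by 2.96 ± 0.03, Fgf10 exceeded Fgf9 by 1.10 ± 0.03, and Tbx4 exceeded Tbx5 by 0.58 ± 0.01. The hedgehog ligand gene Shh lay below its receptor gene Ptch1 at -1.25 ± 0.13, and Vegfa below its receptor gene Kdr at -3.71 ± 0.29. Among globins, the embryonic gene Hba-x relative to the adult gene Hba-a1 was at -7.11 ± 0.23, and Hbb-y exceeded Hba-x by 1.36 ± 0.02. Igf2 exceeded Igf1 by 2.83 ± 0.19 and H19 exceeded Igf2 by 0.18 ± 0.03. Acta2 over Myh11 was 4.03 ± 0.01, Angpt1 over Angpt2 1.06 ± 0.20 and Tgfb2 over Tgfb1 5.23 ± 0.06. Hoxa5 over Hoxa10 was 8.90 ± 2.37, a ratio of uncertain size because Hoxa10 was at 0.10 ± 0.11 TPM. For the mitotic gene Mki67 over the replication gene Pcna the ratio was -2.49 ± 0.06, and with expected counts not divided by length it turned to 0.37. The sign did not hold for Pdgfra over Pdgfrb, at -0.23 ± 0.12, nor for Col3a1 over Col1a1, at 0.31 ± 0.20.

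**Figure D2:**
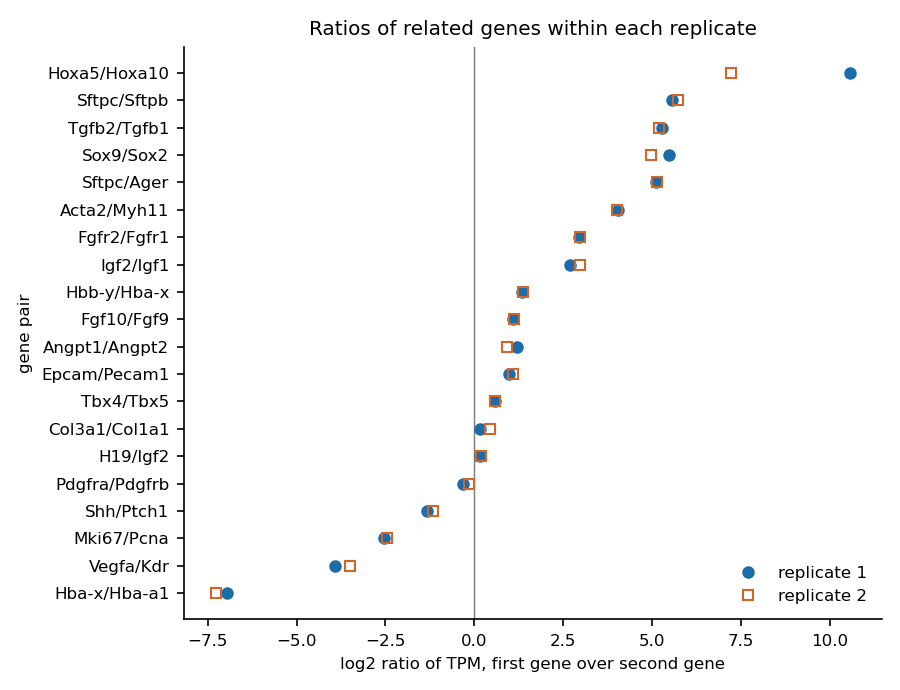
Log2 ratio of TPM for 20 gene pairs within replicate 1 (filled circles) and replicate 2 (open squares), with a line at 0. Most pairs have nearly the same ratio in both replicates, and Hoxa5 over Hoxa10 differs most, at 10.57 in replicate 1 and 7.23 in replicate 2.

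Transcript shares were compared in 15 genes, and in 14 of them the same transcript led in both replicates, the exception being Vegfa. A leading transcript with at least 50% of the TPM of its gene was found in 8 genes. Pkm-201 took 93.5 ± 0.439% of Pkm, Nkx2-1-202 took 91.8 ± 0.867% of Nkx2-1 and Tbx4-203 took 85.0 ± 3.46% of Tbx4. Cd44-207 took 54.6 ± 0.344% of Cd44 and Numb-204 took 59.1 ± 0.272% of Numb. Sftpc, Eln and Notch2 had a single transcript in these tables, so their place among the 14 and the 8 was fixed in advance. Others were divided. Leading shares were 27.3 ± 2.35% for Fgfr2-217, 34.7 ± 0.491% for the leading transcript of Tpm1 and 40.4 ± 3.13% for Foxp1-225. They were 25.0 ± 1.55% for Mbnl1-214 and 39.9 ± 10.5% for Vegfa-201. Fn1-202, annotated as a retained intron, led Fn1 at 32.0 ± 1.46%. Igf2-208, annotated as a processed transcript, led Igf2 at 43.5 ± 2.35%. Shares of transcripts that overlap over most of their length rest on the estimator, most of all in a gene at the level of Vegfa.

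Across the 15493 genes with a mean of at least 1 TPM, log2(TPM + 1) in the replicates had a Spearman rho of 0.984 and a Pearson r of 0.983, correlations across genes, which are not independent replicates. Against counting error alone the chi-square was 11.4 per degree of freedom over 17794 genes, which treats reads as independent molecules and does not separate biological spread from that of library preparation. The biological coefficient of variation was 0.119. The SD of the log2 difference was 0.53 over genes from 1 to 10 TPM, 0.24 from 10 to 100 TPM and 0.15 from 100 to 1000 TPM. The spike-ins gave a like check: over 52 of them with at least 20 counts in both libraries the SD of the log2 ratio was 0.20, and counts of gene RNA per spike-in count were 0.990-fold in replicate 2 relative to replicate 1.

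The clearest differences between the pools lay in genes of organs beside the lung. Liver genes were higher in replicate 2 in 9 of 9 compared members, with a median log2 difference of 2.74, above all 10000 random lists. Afp, the fetal serum protein gene, was at 18.3 TPM in replicate 1 and 155 TPM in replicate 2, its neighbour Alb on chromosome 5 (90460897 to 90476602) at 10.1 and 88.3 TPM, Apoa2 at 11.1 and 93.0 TPM and Ahsg at 7.54 and 63.0 TPM. The deposited credibility bounds for Afp, 16.8 to 19 TPM in replicate 1 and 146 to 154 TPM in replicate 2, did not overlap. The TPM of 155 in replicate 2 lay just above its own bounds, so the bounds are not centred on the TPM given here. Skeletal muscle genes were higher in replicate 2 in 9 of 9 members with a median difference of 1.25, with the actin gene Acta1 at 75.8 and 270 TPM, the perinatal myosin gene Myh8 at 4.09 and 21.1 TPM and Tnni2 at 14.8 and 49.5 TPM. In the lymphoid and thymus list 8 of 8 members were higher in replicate 2, with a median of 0.96, among them Cd3g at 5.19 and 13.8 TPM, the pre-T cell receptor gene Ptcra at 2.36 and 5.97 TPM and the thymic epithelial gene Psmb11 at 0.980 and 3.59 TPM. Cardiac muscle genes went the other way, with a median of -0.36 and 8 of 11 members lower in replicate 2, led by Myh6 at 81.8 and 49.2 TPM, Nkx2-5 at 2.47 and 1.29 TPM and Myl7 at 565 and 377 TPM, while Nppa, an atrial peptide gene, was higher in replicate 2 at 102 and 136 TPM.

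Sex-linked genes differed as well. All 4 Y-linked genes at 1 TPM or more were lower in replicate 2, with a median log2 difference of -1.09, below all 10000 random lists. Ddx3y was at 24.6 TPM in replicate 1 and 10.4 TPM in replicate 2, Kdm5d at 9.73 and 3.32 TPM, Uty at 12.6 and 5.69 TPM and Eif2s3y at 32.3 and 17.4 TPM. Xist, which coats the inactive X chromosome of females, was at 16.3 and 33.9 TPM. Of the other genes on the X inactivation list, Jpx, Tsix and Ftx differed by 0.25, 0.23 and -0.08, and the list median of 0.24 lay inside the random range, but outside it on the higher side under 5 of the other settings.

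Differentiation genes of the epithelium, and basal cell genes, were higher in replicate 2 and tip progenitor genes lower. All 13 type 2 and surfactant genes were higher in replicate 2, with a median log2 difference of 0.27, and Sftpd, Slc34a2, Napsa and Sftpa1 differed most, by 0.80, 0.65, 0.56 and 0.45. Type 1 genes had a median of 0.25 with 8 of 10 members higher, led by Aqp5 at 0.46 and Hopx at 0.38. Airway secretory genes had a median of 0.43 with 8 of 8 higher, led by Scgb3a1 at 1.70, Scgb1a1 at 0.96 and Cbr2 at 0.84. Ciliated genes had a median of 0.21 with 8 of 9 higher. Basal genes had one of 0.76 with 6 of 6 higher, nearer to the 0.96 of the lymphoid and thymus list than to the alveolar medians. Whether the basal difference arose in lung epithelium or in neighbouring tissue was not tested. The general epithelial list differed by 0.11, lung fluid and ion transport genes by 0.18 and glucocorticoid response genes by 0.12. Distal tip progenitor genes had a median of -0.17 with 8 of 11 lower in replicate 2. Etv4 at -0.36, Sox9 and Nkx2-1 at -0.29 and Mycn at -0.25 led these. The other members, Foxp2, Shh and Bmp4, were higher in replicate 2, by 0.16, 0.15 and 0.05. The pool with the higher differentiation genes, replicate 2, was also the pool with the lower Y-linked genes and the higher liver, skeletal muscle, and lymphoid and thymus genes.

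Smaller differences covered blood, mesothelial and other genes. Erythroid genes had a median log2 difference of 0.27, in which the erythroid precursor genes Klf1 and Slc4a1 differed by 1.17 and 0.94 and Hba-a2 by 0.14, beside the higher liver genes of the same library. Macrophage and myeloid genes were higher in replicate 2 in 12 of 12 members with a median of 0.16, mesothelial genes in 5 of 5 with 0.24, nuclear long noncoding genes in 5 of 6 with 0.28 and imprinted genes in 10 of 16 with 0.09. Mitochondrially encoded genes were lower in replicate 2 in 13 of 13 members with a median of -0.25, led by mt-Nd4l at -1.52 and mt-Co3 at -0.60. The size of this difference is uncertain: the deposited credibility bounds of mt-Co3 were 889 to 5867 TPM in replicate 1 and 794 to 6398 TPM in replicate 2, the pseudogene Gm28437 differed the other way by 0.11, and among list levels the mitochondrially encoded list was at 1789 with the posterior mean TPM in place of 1207 TPM. RNAs without a poly(A) tail at 0.12, cartilage genes at -0.16 and BMP and TGF-beta genes at -0.10 stood apart as well, but fell inside the random range under 5, 4 and 2 of the other settings. Endothelial, mesenchymal, smooth muscle, pericyte, matrix, proliferation, ribosomal protein and housekeeping genes, and 16 other lists, lay inside the random range. Of those 16, the X inactivation list moved outside it under 5 other settings, immediate early genes under 3, interferon response genes under 2 and Hox genes of groups 1 to 6 under 1. In all, 23 of 47 lists stood apart, 17 higher and 6 lower in replicate 2, where 2.35 would be expected of random lists. Lists hold genes that vary together and share some members, so the number exceeds chance more readily than independent genes would.

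**Figure D3:**
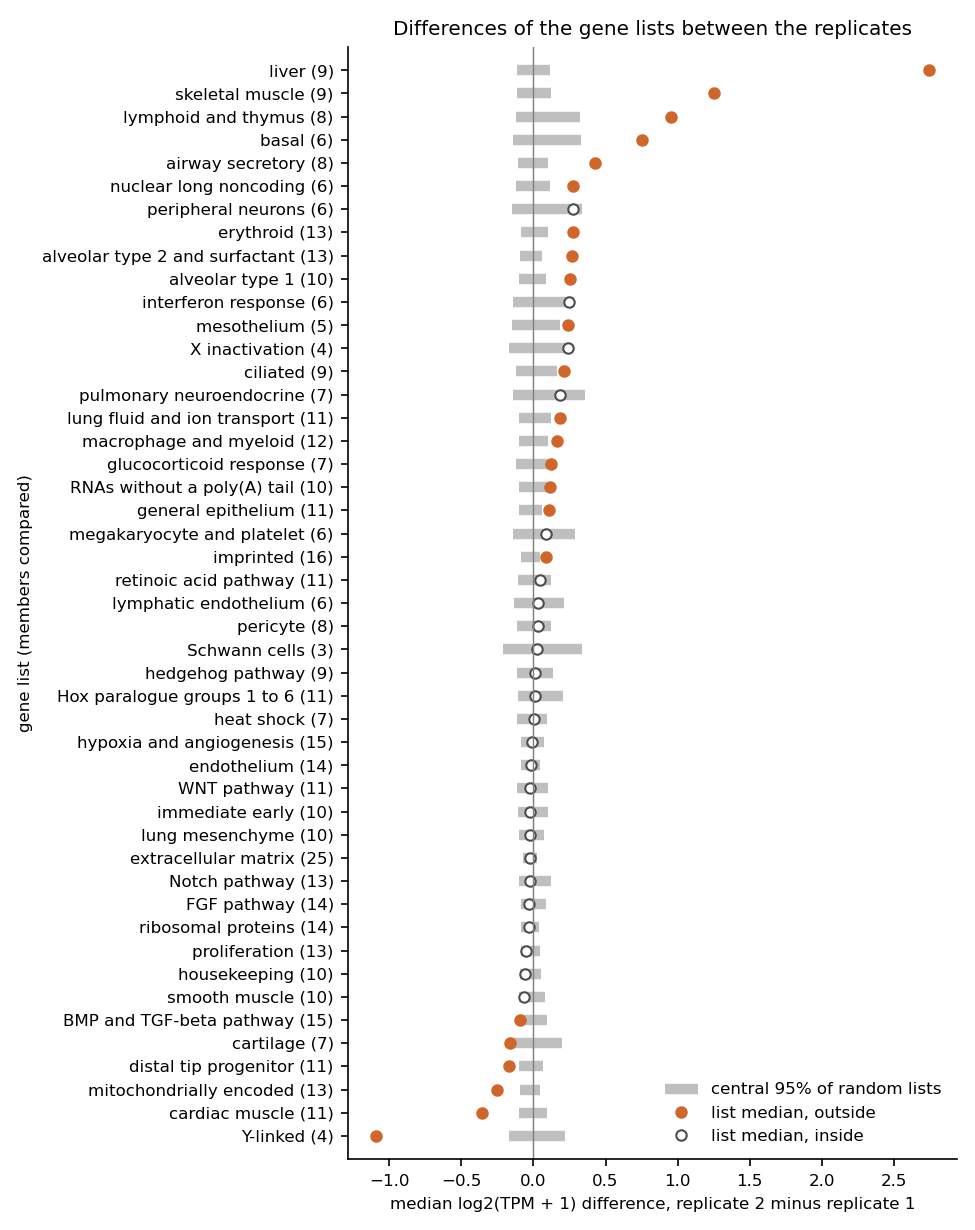
Median log2(TPM + 1) difference of 47 gene lists, replicate 2 minus replicate 1, with the grey bar giving the central 95% of 10000 random lists matched on mean expression. Liver at 2.74, skeletal muscle at 1.25 and lymphoid and thymus at 0.96 lie farthest to the right and Y-linked genes at -1.09 farthest to the left.

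**Figure D4:**
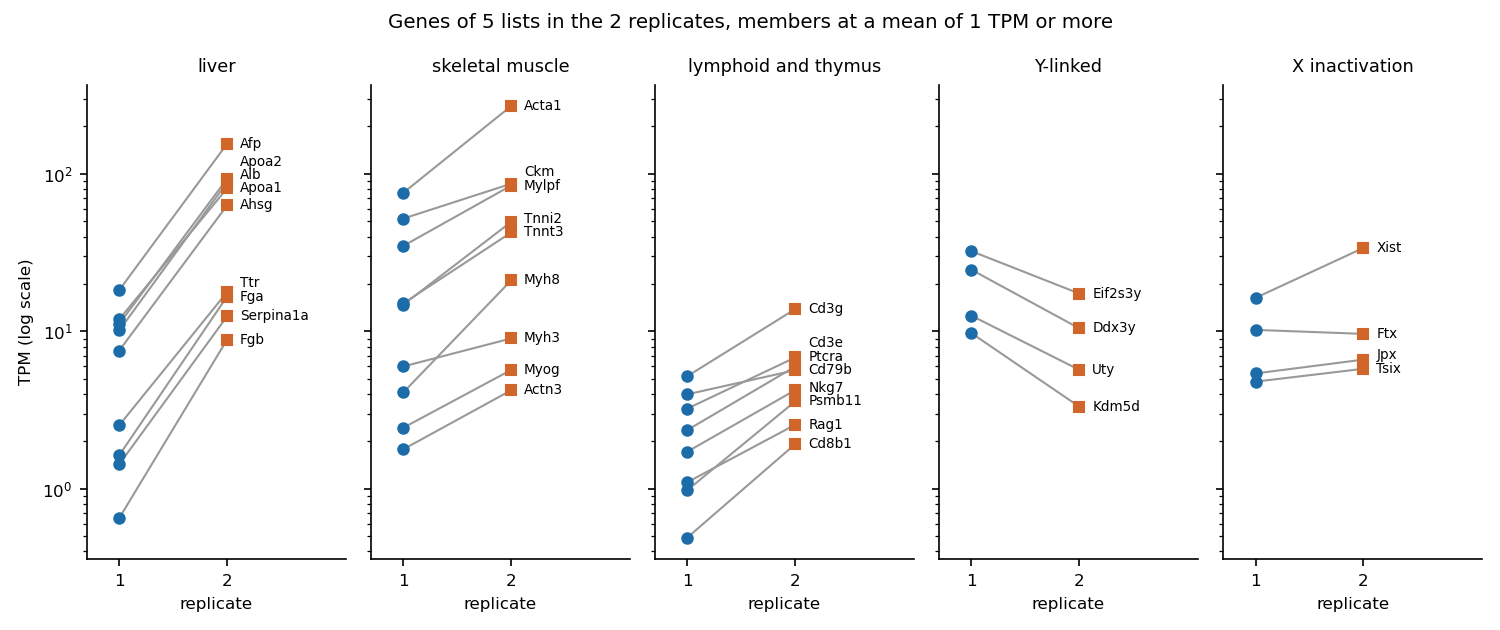
TPM on a log axis of the members of 5 lists at a mean of at least 1 TPM, with a line joining each gene in replicate 1 (circles) and replicate 2 (squares). All compared liver, skeletal muscle, and lymphoid and thymus genes are higher in replicate 2, all Y-linked genes are lower, and Xist is higher.

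Among single genes with a mean of at least 5 TPM, the bone matrix genes Spp1 and Ibsp, which lie near each other on chromosome 5, were among the 8 that differed most in the lower direction. Spp1 was at 76.2 TPM in replicate 1 and 3.79 TPM in replicate 2, and Ibsp at 48.3 and 9.68 TPM. In the higher direction the 8 genes included Afp and Alb, with log2 differences of 3.02 and 3.0. The other 12 were 8 small RNA genes with at most 26.9 expected counts in either replicate, the pseudogenes Gm14539 and Rpl21-ps15, the coding gene Gm10273, and a gene with no match in the later annotation, at 114 expected counts in replicate 1 and 0 in replicate 2. Gm22333 was listed at 0.98 expected counts in replicate 2 and 0 in replicate 1, Mir134 at 0.98 in replicate 1 and 0 in replicate 2, and the pseudogene Gm14539 at 10.9 and 105. The deposited credibility bounds of Gm10273 overlapped, at 7.31e-06 to 4.09 TPM in replicate 1 and 0.176 to 17.5 TPM in replicate 2. Those of Rpl21-ps15 overlapped as well, while those of Gm14539 and of the gene with no match did not. Counted over all 15493 genes, 413 differed by 2-fold or more, 298 higher and 115 lower in replicate 2. Of these, 167 code for protein (142 of them higher in replicate 2), 138 are small RNA genes and 86 are pseudogenes. The small RNA genes had a median of 1 expected count in replicate 1, and 69 of the 138 were higher in replicate 2. For the pseudogenes the median was 21.4 expected counts and for the coding genes 52. Counting error alone gave a median of 98.5 such genes in 20 simulations, which left out error in the division of reads among copies. With TMM-scaled expected counts, which are not divided by length, the count was 174, of which 149 were higher and 25 lower. So 85.6% were higher in place of 72.2%. The TPM count of 167 coding genes was divided in nearly the same way, with 142 higher and 25 lower.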

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

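Among rows that entered no comparison, the 26248 rows named only by numbers carried 74.3 expected counts in replicate 1, on 6 rows, and 74 in replicate 2, on 4 rows. Both totals exceed the limit of 3 counts that a count of 0 allows. What these rows stand for is not stated in the sources used here, and they held 0.000191% and 0.000273% of the counts.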

How the results depend on the processing

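The restriction to genes coding for protein and the correction for gene length and GC content were chosen after the data were seen. The numbers of genes detected, lists standing apart, pairs with a held sign, lists with a median of 1 TPM or more and genes with a leading transcript stayed within 1.5 times of their values under every alternative run. Without replicate 1 or without replicate 2, detection ranged from 15181 to 15709 genes, 46 lists had a median of 1 TPM or more and 8 genes a leading transcript, while lists standing apart and held signs need both replicates. The number of genes differing by 2-fold varied more: against 413 it was 659 with a pseudocount of 0.1, 134 with a minimum of 5 TPM, 174 with TMM scaling, 174 with DESeq2 size factors, 175 with spike-in scaling and 167 among coding genes. At a threshold of 1.5-fold it was 935 and at 4-fold 140. The TMM factors were 0.992 and 1.008, and all scalings of expected counts gave nearly the same count. Scaling factors therefore do not account for the drop to 174. Expected counts are not divided by length, and the 138 small RNA genes among the 413 had a median length of 124.5 nt. The values point to the missing division by length, although the genes lost were not listed. The cause of the other changes was not tested. Spearman rho was 0.953 without a minimum on TPM and 0.985 with a minimum of 5 TPM, where Pearson r was 0.993 and 0.986, and r was 0.959 with a pseudocount of 0.1. Coding genes took 81.7% of TPM in place of 92.5% of counts, because TPM divides by length. The biological coefficient of variation was 0.133 without a filter on low counts, and the square root of the DESeq2 median gene-wise dispersion was 0.0001, at the lower bound of that estimator, for a reason that was not tested. Single list levels moved by more than 1 SD in 15 lists with the posterior mean TPM, 27 without spike-ins and mitochondrial genes and 41 with FPKM. The last 2 settings multiply all genes of a library by 1 factor. Whether a list moved under them depended on how small its SD was relative to its level, and the order of the genes within a library stayed the same. With the posterior mean TPM the list levels of kidney, thyroid, Hox paralogue groups 7 to 13 and Schwann cells were 0.13, 0.325, 0.145 and 1.52. With expected counts, which are not divided by length, the ratio of Mki67 to Pcna reversed to 0.37 and 18 of the other 19 gene ratios moved by more than 1 SD. Among these the ratios whose sign did not hold changed sign, Pdgfra/Pdgfrb to 0.05 and Col3a1/Col1a1 to -0.15. With the posterior mean TPM 3 ratios moved. Single lists changed side of the random range in 22 recomputed differences, 11 each way, and none that stood apart reversed its sign. With 27145411 counts in the shallower library, 2-fold differences below 10 TPM are the least certain, with 340 of the 413 in that range.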

Other observations

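The tests of gene length and GC content, of the share of epithelium and of the share of males behind the differentiation genes, and the exon comparison, were chosen after the results were seen. The other tests were set before the data were examined.

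Exons that exclude each other divided the transcripts of Pkm and Fgfr2. In Pkm, on chromosome 9 (plus strand, build mm10), the downstream exon of the pair (59675568 to 59675734), which defines the M2 form of pyruvate kinase found in proliferating and embryonic tissue, was in transcripts with 93.5 ± 0.439% of the TPM, and the upstream exon (59675029 to 59675195), which defines the M1 form of muscle and brain, in 6.48 ± 0.439%. In Fgfr2, on chromosome 7 (minus strand), transcripts with the upstream exon (130199758 to 130199905), which encodes the IIIb form of epithelium that binds FGF10, took 78.5 ± 2.96% of the TPM carrying either exon, at 51.1 ± 2.35 TPM, and those with the downstream exon (130198419 to 130198563), of the IIIc form of mesenchyme, took 21.5 ± 2.96%, at 14.0 ± 1.81 TPM. Of the whole Fgfr2 level these were 30.7 ± 0.75% and 8.40 ± 1.27%, and the rest, with the leading transcript Fgfr2-217 at 27.3 ± 2.35%, carried neither exon, so the forms were resolved for the smaller part of the gene. Exons were read from the later annotation, in which the M1 transcript of Pkm and the highest IIIb transcript of Fgfr2 have another length than in the deposited tables. That IIIb transcript held 33.6 of the 49.5 TPM of the IIIb exon in replicate 1 and 32.45 of 52.8 TPM in replicate 2, and 7 of the 10 IIIb transcripts were listed at 0, so most of the IIIb value rests on a transcript whose structure differs between annotations.

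Y-linked genes were lower and Xist higher in replicate 2. All 4 Y-linked genes at 1 TPM or more differed together and opposite to Xist, as an unequal share of male embryos requires, so a lower share of males in the pool of replicate 2 is a candidate explanation. The Y-linked median was -1.04 after correction for gene length and GC content, against -1.09 before. The bin medians of these trends lay between -0.03 and 0.25, too small to account for the difference. The correction could therefore not have brought the list inside the random range. The number of embryos of each sex is not given in the labels, and no biological difference beyond the pools was tested.

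Liver, skeletal muscle, and lymphoid and thymus genes were higher in replicate 2. As the reading of unequal carry-over of neighbouring tissue requires, 3 of 5 such lists, written before the data were examined, lay outside the random range with at least 80% of members in one direction, so unequal carry-over at dissection may account for these 3. Cardiac muscle lay outside the random range the other way, at -0.36 and in 9 of 9 settings, with 72.7% of its members lower in replicate 2, so more carry-over of every neighbour in that pool is not what the values show, and no thyroid gene reached 1 TPM. All 3 lists stayed outside the random range after correction for gene length and GC content. Over 20 bins the medians ran from -0.03 to 0.25 for length and from -0.03 to 0.03 for GC content. Trends of that size are too small to account for the 3 differences. The correction could not have brought the lists inside the range, so its outcome adds nothing further. No member of these lists is on another list, the labels give no sorting of cells that would remove such tissue, and expression of the same genes within the lung itself stays open.

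Type 1 and type 2 genes were higher and tip progenitor genes lower in replicate 2. Both alveolar medians lay above the random range and the tip median was -0.17, below it, so a pool at a slightly later stage of development may account for the pattern. The tip list was not uniform, as Foxp2, Shh and Bmp4 were higher in replicate 2. Whether each of its members, among them the lung lineage factor Nkx2-1, tracks tip progenitors alone was not tested. A larger share of epithelium in replicate 2, as the whole cause, would move tip genes the same way. The type 2 median exceeded the tip median by 0.44 (95% bootstrap interval over members 0.22 to 0.70). That interval covers the spread among the listed genes and not that between pools. The values argue against this share as the whole cause only if the tip list tracks epithelium alone, which was not tested. It stays open as a part, as the general epithelial list was higher in replicate 2 by 0.11 in 8 of 11 members. That list lay outside the random range in 9 of 9 settings. Its 3 lower members were Epcam at -0.004, Cdh1 at -0.045 and Cldn6 at -0.097. An unequal share of male embryos cannot be told apart from a later stage with 2 pools, as the pool with lower Y-linked genes was also the pool with higher alveolar genes. Of the listed genes, 1 of 13 type 2 and 1 of 10 type 1 genes and 3 of 11 tip genes are also on other lists.

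Priming on poly(A) tails would leave RNAs without such a tail low. Their list had a median of 37.8 TPM (38.9 and 36.7 in the replicates). This lay above the median of 19 ± 0.163 TPM over 13197 detected coding genes, so the predicted lower median was not seen. The comparison cannot decide on priming, because the amount of these RNAs in the tissue is not known and TPM weights short RNAs more. A lower yield of these RNAs stays open. Low members were found on both sides of the size limit of 200 nt stated in the labels: the shorter Rny3 was listed at 0 and Rny1 at 0 and 4.15 TPM, and the longer Terc at 0.35 and 0 TPM and Rmrp at 3.98 and 4.35 TPM, the last 2 named after the values were seen.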
